A study of Homo sapiens with 18 samples.

How the data were processed

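Human keratinocytes in primary culture, with RNA of 3 donors pooled at each time point, were followed as they grew to confluence and beyond it, with day 0 as the day of confluence. The data are 18 Affymetrix gene chips. In a first study the RNA of days -2, 0, 1, 2 and 3 was hybridised to the U133A and the U133B array. In a second study the U133A2 array, which carries nearly the same probe sets as U133A, was used for days -3, -2, -1, 0, 1, 2, 3 and 5. Each day thus has 1 array per array type. Because RNA was pooled, no value belongs to a single donor, and no spread between donors can be had.

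The deposited values are signal intensities on a linear scale, made with MAS5 per the submitters' processing notes. No version is given in the sources used here. MAS5 subtracts a local background, combines the perfect-match and mismatch probes of each probe set and scales each array to a common mean. The deposited values fit such scaling, since the mean of each array between its 2nd and 98th percentile was close to a common value, 499.75 on the U133A array of day -2. Such scaling hides a change in the total mRNA of a cell. Scanner files and detection calls were not used here, so no probe set could be called absent. The number of arrays limits the precision.

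From these intensities, log2(signal + 16) was computed, and fold changes are on that scale, which understates the change of dim genes. Of the genes named below on the U133A and U133A2 arrays, AKR1C3, ALOX12B, ARG1, AZGP1, BBOX1, CDHR1, CHP2, CTSZ, CYP4B1 and DCBLD2 had a mean signal under 32 in at least 1 study on the low side of their change, so that the pseudocount sets much of its size. The U133A and U133A2 tables share 22277 probe sets. Control probe sets were left out. On the annotation of these arrays 19070 probe sets had 1 gene symbol, 1043 had several and 2108 had none or were not listed. On U133B these numbers were 15432, 554 and 6597. Symbols were checked through Entrez gene identifiers against a RefSeq table of GRCh38.p14, in which 19058 and 15407 of the probe sets with 1 symbol were found. That table was used for names alone, and no coordinates are given. For each gene the probe set with the highest mean was kept. Genes below the 40th percentile of all non-control probe sets were removed, which left 7911 of 11963 genes on the U133A and U133A2 arrays and 7076 of 9794 genes on U133B. Of 31 genes named below with more than 1 probe set above that limit, 0 had a probe set of the opposite sign. SERPINB3 and SERPINB4, and AKR1C1 and AKR1C3, are close paralogs whose probes may not tell them apart.

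Tests were made with limma 3.58.1 in R 4.3.3, with variances moderated along the mean signal and Benjamini-Hochberg adjustment at 0.05. The main comparison set the 7 arrays after confluence (days 1, 2, 3 and 5) against the 4 arrays before it (days -3, -2 and -1), with day 0 (2 arrays) as its own phase and the array type as a block, on 13 arrays with 9 residual degrees of freedom. Different days of a phase serve as the spread in this fit. A second fit took each day as a level, again with the array type as a block, with 4 residual degrees of freedom. The block comes from the array type, which carries the study, and not from a pairing of cultures. U133B was fitted with a slope over the 5 days, with 3 residual degrees of freedom. The sources do not say whether the second study used cultures of its own or RNA of the first. Day 1 argues against the same RNA: 34 mitosis genes changed from day -2 by a mean of 0.06 in the first study and -1.66 in the second. Changes at day 1 correlated at 0.377 between the studies across 7911 genes. The same RNA on U133A and U133B gave 0.680, though on 100 shared probe sets. The p-values measure the spread between arrays, in which technical and culture differences cannot be separated. Python 3.11.15 and matplotlib 3.10.9 drew the plots.

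A total of 28 gene lists holding 731 genes were fixed before the data were examined, as were the designs, the alternatives and the rule for named genes. The 26 lists with at least 5 measured genes were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes and with an estimated correlation as the alternative. In the main comparison that estimate also counts members that move together over the days of a phase. Markers of immune and of endothelial cells had fewer than 5 measured genes and were not tested.

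The rule for named genes took the 12 largest rises and 12 largest falls after against before confluence among genes past the threshold with the same sign in both array types. It also took the 3 members of each list with the smallest adjusted p past the threshold, 10 keratinocyte markers (1 of them is not reported here), and the 5 largest rises and 5 largest falls past the threshold at each shared day against day -2. From days measured once it took the 3 largest rises and 3 largest falls past the threshold. From U133B it took the 8 largest rises and 8 largest falls of day 3 over day -2 among genes past the threshold. Genes that passed at day 0 or day 1 and lay beyond both day -2 and day 3 were to be named as transient. The count made was stricter, since the difference from day 3 also had to pass the threshold, and it gave 0. Genes that lay beyond day 3 without passing that second test were not counted or named as transient. XIST, Y-linked genes and probe sets with several symbols or none were never named.

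The alternatives tried were other pseudocounts, scalings, filters, probe set rules and variance models, the fit with no block, each array left out, each study alone, other placings of day 0, a slope over days, the 5 shared days alone and a 2-fold limit. The fits were tested on simulated arrays with the means and residual spread of the real ones, but with far fewer changed genes. After against before confluence 60, 58 and 51 genes were changed 2-fold, 4-fold and 16-fold, where the real fit called 2819. Adjusted p values depend on how many genes change, so the shares called need not hold for the real data. After against before confluence, with 7903 genes in the fit, 70.0% of the genes changed 2-fold and 94.8% of those changed 4-fold were called. For day 3 against day -2, with 7907 genes, these shares were 12.9% and 66.7%. For the U133B slope, with 7035 genes, 0% of the genes changed 2-fold, 10.3% of those changed 4-fold and 64.4% of those changed 16-fold were called. The smallest simulated size was raised to 2-fold, and the 16-fold size was added, after a first run on simulated arrays called no changed gene in the U133B fit. A planted list was called and 0 of 100 random lists were, on simulated genes that vary independently of one another.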

Results

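Gene expression was measured by microarray in primary human keratinocytes that differentiate once they fill the culture dish. RNA pooled from 3 donors was taken at days counted from confluence. The first study covered days -2, 0, 1, 2 and 3 on the U133A and U133B arrays, and the second covered days -3, -2, -1, 0, 1, 2, 3 and 5 on the U133A2 array. There was 1 array for each day and array type, 18 in all. Values are the deposited MAS5 signals, given below as log2 fold changes with their standard error (SE) from limma or as mean signal ± SD over the arrays of a phase.

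The first question was which genes differ after confluence from before it. Among the largest rises, BBOX1, which makes carnitine, rose by 5.24 (SE 0.47, adjusted p = 5.44e-05). The desmosomal cadherin DSC1 rose by 5.12 (SE 0.40, adjusted p = 1.65e-05), and its signal in the second study went from 287 ± 118 (SD, n = 3) to 9980 ± 2203 (SD, n = 4). The cytochrome CYP4B1 (5.19), the keratin KRT4 (4.69), CHP2 (4.48), the growth factor binding protein IGFBP3 (4.41), the cornified envelope protein LORICRIN (4.27) and the filaggrin gene FLG (4.11) followed, and then AZGP1 (4.01), CALML5 (3.99), the late envelope gene LCE2B (3.93) and the arginase ARG1 (3.89). Before confluence CHP2 (3.30 in the second study) and AZGP1 (7.91), and in the first study BBOX1 (4.15) and ARG1 (14.4), had signals under the pseudocount of 16, which thus sets the size and order of their changes. With a pseudocount of 64 these were 3.02 for CHP2, 2.75 for AZGP1, 4.04 for BBOX1 and 2.83 for ARG1.

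Among the largest falls, the protease inhibitor TFPI2 fell by 3.79 (SE 0.84, adjusted p = 0.0042), and its signal in the second study went from 1675 ± 242 (SD, n = 3) to 120 ± 125 (SD, n = 4). The membrane protein DCBLD2 fell by 3.30, FOXM1, a transcription factor of mitotic genes, fell by 3.23, the spindle protein TACC3 fell by 3.20 and the cell cycle factor MYBL2 fell by 3.16. The thrombospondins THBS1 and THBS2 changed by -3.12 and -3.08, the simple epithelial keratin KRT7 by -3.08 (SE 0.24, adjusted p = 1.65e-05), the helicase subunit CDC45 by -2.98, the phosphatase DUSP4 by -2.93, the mitotic activator CDC20 by -2.90 and the ErbB ligand NRG1 by -2.86.

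In all, limma called 1326 genes higher and 1493 lower of 7911 tested, 573 and 575 of them by 2-fold or more. The change had the same sign within both studies for 1273 of the higher and 1444 of the lower genes. With no replicate block for the array type there were 790 genes higher after confluence and 952 genes lower after confluence. On the U133A arrays alone, with 1 array before confluence, limma called 0 (617 at an unadjusted p under 0.05). In the second study the ratio of 3′ to 5′ signal of the ACTB control, a measure of RNA integrity, lay between 1.09 and 1.22 before confluence, between 1.64 and 1.84 at days 1, 2 and 3, and at 1.33 at day 5, so that it moved with the phase and with each gene group below. Without these 3 arrays, an alternative chosen after seeing the data, 575 genes were called higher and 673 lower. In the first study the ratio on U133A ranged from 1.07 to 1.46 over its 5 days. The same ratio of the GAPDH control in the second study lay between 1.08 and 1.12 before confluence and between 1.20 and 1.37 after it, highest at day 3, and in the first study on U133A between 0.821 and 0.963.

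The keratinocyte markers are genes of known epidermal layers. KRT5 and KRT14, the keratins of the basal layer, did not pass the test, at 0.15 (SE 0.16, adjusted p = 0.485) and 0.06 (SE 0.15, adjusted p = 0.78). Over the 13 arrays KRT14 read 75% to 100% of the highest signal of its array and KRT5 58.1% to 98.3%. Whether such bright signals saturate was not tested, so a lack of change cannot be read from them. The suprabasal keratins KRT1 and KRT10 rose by 3.89 (SE 0.47, adjusted p = 0.000176) and 2.58 (SE 0.25, adjusted p = 6.19e-05). They reached up to 84.9% and 72.2% of the highest signal of an array, inside the range of KRT5. Saturation was not tested here either, which limits how far the sizes of these rises can be read. The envelope precursor IVL rose by 1.56 (SE 0.45, adjusted p = 0.0166), a call lost in 4 of 30 alternatives, and the crosslinking enzyme TGM1 by 2.59 (SE 0.33, adjusted p = 0.000216). MKI67, a marker of dividing cells, fell by 2.06 (SE 0.36, adjusted p = 0.00115).

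**Figure D1:**
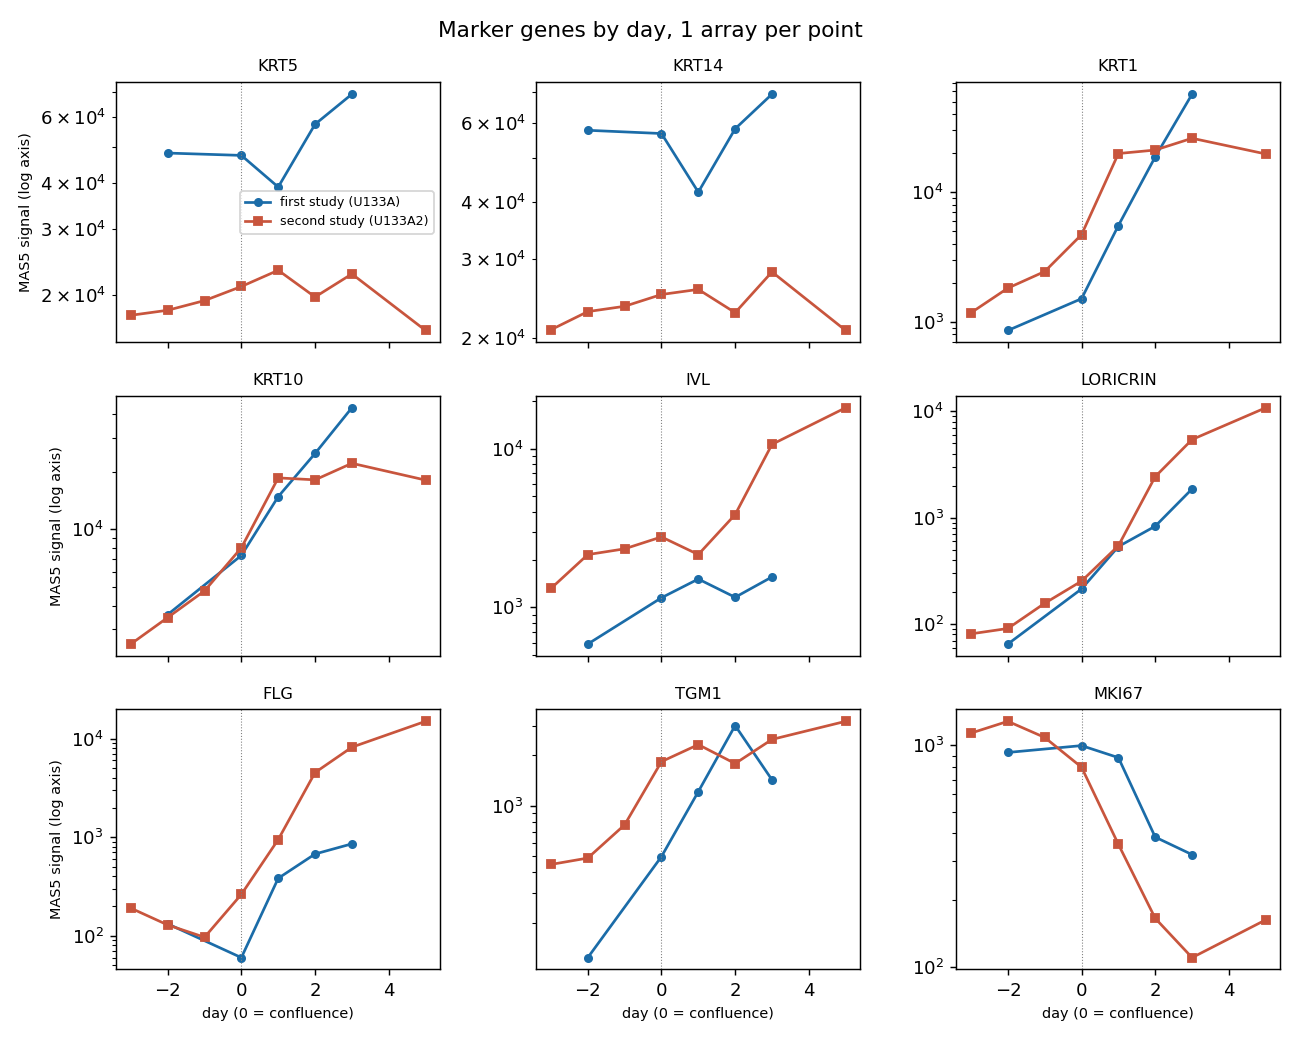
MAS5 signal (log axis, intensity units) of 9 keratinocyte markers against the day from confluence, with 1 point per array, circles for the first study and squares for the second. KRT1, KRT10 and LORICRIN climb through confluence in both studies, KRT5 and KRT14 lie near the highest signal of each array, and the level of a gene is not comparable between the array types.

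The second question was which groups of genes moved together. Of 19 measured genes of the cornified envelope and late differentiation, 18 rose, with a median of 2.26 over the list. They include PPL (2.26), EVPL (2.30) and SCEL (2.97), which encode envelope proteins. All 16 suprabasal keratin and desmosome genes rose (median 1.35), DSG1 by 3.74. Of 22 epidermal proteases and inhibitors 17 rose and 2 fell (median 1.22), with SERPINB3 at 3.23, SERPINB4 at 3.10 and the kallikrein KLK11 at 2.37. Camera gave adjusted p values of 2.04e-10, 6.2e-11 and 9.05e-07 for these lists, and adjusted p = 0.174 with an estimated correlation for each.

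Other groups with more rises than falls were the antimicrobial genes, with 7 of 10 higher and 0 lower (median 1.51), among them the defensin DEFB1 (3.75), SLPI (1.97) and the galectin LGALS3 (1.03). Of 20 differentiation transcription factors 14 rose and 1 fell (median 1.11), with KLF4 at 2.74, GATA3 at 1.63 and CEBPA at 3.08. Of 29 genes of lysosome and autophagy 15 rose and 2 fell (median 0.65), with GABARAP at 1.02 and the protease CTSA at 1.34, while the protease CTSZ fell by 1.48. Camera gave adjusted p = 9.69e-05, 7.66e-08 and 6.09e-05, and adjusted p = 0.174 with an estimated correlation for each. Of 17 genes on the list barrier lipid synthesis 9 rose and 2 fell (median 0.53, camera adjusted p = 0.0185, and adjusted p = 0.31 with an estimated correlation). The higher genes include the sphingolipid hydrolases SMPD1 (1.37) and ASAH1 (1.54), so the list does not stand for synthesis alone. They also include the lipoxygenase ALOX12B (3.57, with a first-study signal of 6.97 at day -2, under the pseudocount).

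Genes of the cell cycle fell. All 34 measured mitosis genes fell, with a median of -2.25, for example the kinesin KIF23 (-2.83), the kinetochore motor CENPE (-2.78) and the kinase AURKB (-2.42). Of 29 genes of DNA replication 27 fell and 0 rose (median -1.78), with CDC6 at -2.26, GINS1 at -2.07 and CDC45 at -2.98. Of 23 ribosome biogenesis genes 20 fell and 0 rose (median -0.82), with MRTO4 at -1.40, NIP7 at -1.07 and WDR12 at -0.95. Camera gave adjusted p = 8.49e-14, 5.5e-13 and 7.32e-09, and with an estimated correlation adjusted p = 0.318, 0.213 and 0.2. Of 13 genes of activated and wound keratinocytes 7 fell and 1 rose (median -0.92, adjusted p = 0.0253, and adjusted p = 0.454 with an estimated correlation), with the protease PLAU at -2.15 and the collagenase MMP9 at -2.34. The gene of this list that rose was the keratin KRT16 (1.56), looked up after the data had been seen. Without the first-study array of day -2 that list (activated keratinocyte and wound) had an adjusted p = 0.137.

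Small shifts and mixed groups made up the rest. None of 26 ribosomal protein genes passed the test alone, yet camera called the list ribosomal proteins higher (median 0.32, adjusted p = 0.00162), with adjusted p = 0.646 with an estimated correlation, 0.0900 without the first-study array of day -2 and 0.0778 after quantile normalization. Of the 6 melanocyte markers 4 rose (median 1.16, adjusted p = 0.0185, and adjusted p = 0.454 with an estimated correlation), with MITF at 1.22, PMEL at 1.60 and MLANA at 1.33. Among 12 fibroblast markers 2 rose and 3 fell (adjusted p = 0.666): the proteoglycan DCN rose by 2.70 (SE 0.48), S100A4 rose by 0.97, and vimentin, VIM, fell by 2.85 (SE 0.53). Of 19 genes of basal keratins and matrix adhesion 7 fell and 1 rose (adjusted p = 0.141), with FERMT1 at -1.11, ITGA2 at -2.24 and DST at 0.80.

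Several lists did not pass although single members did. Of 24 genes of the unfolded protein response 8 fell and 3 rose (adjusted p = 0.102), with the chaperones HSP90B1 at -1.87 and CALR at -1.10 and SDF2L1 at -1.56. Of 19 p53 targets and arrest genes 7 rose and 3 fell (adjusted p = 0.19), with the cell cycle inhibitors CDKN1B at 1.15 and CDKN1C at 2.24 and SESN1 at 1.33. Of 21 immediate early genes 7 rose and 5 fell (adjusted p = 0.544), with DUSP1 at 2.46 and ZFP36 at 1.24, and the median of 0.07 and the mean of -0.05 differed in sign. Of 15 genes of NF-kB and cytokines 4 rose and 2 fell (adjusted p = 0.936), with the chemokine CXCL14 at 3.14, the interleukin 1 antagonist IL1RN at 1.48 and the inhibitor TNFAIP3 at -1.53, and here the median was -0.27 and the mean 0.12. Of 23 genes of hypoxia and glycolysis 6 rose and 4 fell (adjusted p = 0.49), with the peptide hormone ADM at 2.93, NDRG1 at 1.54 and ALDOC at 0.83.

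Of 20 genes of the NRF2 response 5 rose and 3 fell (adjusted p = 0.321), with AKR1C1 at 2.81, AKR1C3 at 2.28 and GPX3 at 1.61. Of 18 cholesterol synthesis genes 3 rose and 4 fell (adjusted p = 0.792), with TM7SF2 at 2.36, SC5D at 0.98 and ACAT2 at -0.90. Of 14 Notch pathway genes 3 rose and 2 fell (adjusted p = 0.321), with the receptors NOTCH2 at 1.04 and NOTCH3 at 2.32 and the target HES1 at 0.83. Of 11 genes of retinoid metabolism 5 rose and 3 fell (adjusted p = 0.421), with the binding protein CRABP2 at 2.14, the receptor RXRA at 1.58 and TGM2 at -1.66. Of 28 interferon response genes 1 rose and 3 fell (adjusted p = 0.321), with OAS1 at 0.59, IFI35 at -1.11 and OAS3 at -0.91. Of 30 genes of oxidative phosphorylation 4 rose and 1 fell (adjusted p = 0.321), with SDHD at 0.58, COX5B at 0.61 and NDUFS1 at -0.38.

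In total camera called 13 of 26 lists, 9 higher and 4 lower, with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.174). Among 100 splits of the arrays 30 gave as many called lists, the real split included, so the number of called lists is no evidence beyond chance. By the size of the median of a single list, fewer than 5 of the 100 splits were as large as the real one for 10 of the 13 called lists, and 5 or more for activated keratinocyte and wound (5), barrier lipid synthesis (5) and ribosomal proteins (11). With arrays exchanged within each study, the count for activated keratinocyte and wound was 3 of 100. Adjusted over the list alone, the counts were those above except that 8 antimicrobial genes, 15 differentiation transcription factors, 19 lysosome genes and 8 hypoxia genes were higher. On that count 21 ribosome biogenesis, 4 p53, 4 fibroblast and 2 interferon genes were lower, and 0 genes of oxidative phosphorylation passed in either direction.

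**Figure D2:**
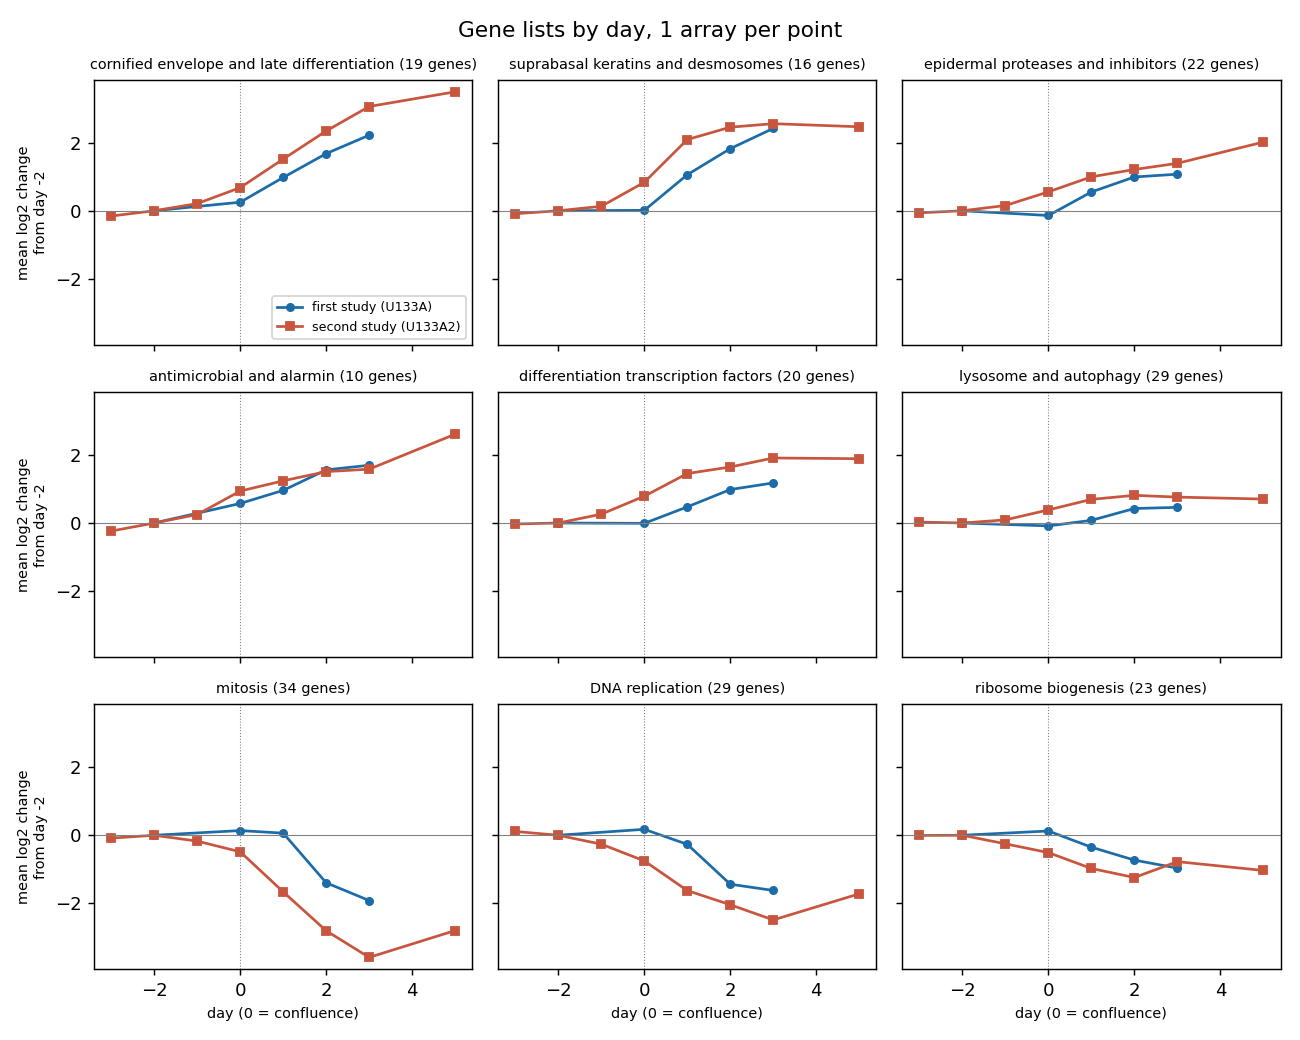
Mean log2 change from day -2 of the genes of 9 lists against the day from confluence, with 1 point per array, circles for the first study and squares for the second. The mitosis list, of 34 genes, drops after day 1 in the first study and from day 0 in the second.

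The third comparison followed the change day by day against day -2. At day 0 limma called 0 genes (211 at an unadjusted p under 0.05, smallest adjusted p = 0.183). At day 1 it called 13 higher and 5 lower, at day 2 503 and 463, and at day 3 676 and 813. DSC1 stood at 4.22 at day 1, 5.44 at day 2 and 5.98 at day 3, and BBOX1 at 4.44, 5.52 and 6.23. Also called at day 1 were DEFB1 (2.74), SERPINB4 (2.74) and the transcriptional repressor BCL6 (2.66), and in the other direction KRT7 (-2.57), MMP9 (-2.33), FOXD1 (-2.06), TNFAIP3 (-1.87) and PLAU (-1.66).

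At day 2 CHP2 (4.85), IGFBP3 (4.79) and CDHR1 (4.66, from a first-study signal of 20.1, near the pseudocount) were among the largest rises, and TFPI2 (-4.38), DCBLD2 (-3.87), the matrix protein gene CCN2 (-3.76), CDC45 (-3.73) and MYBL2 (-3.72) were the largest falls. At day 3 KRT4 (5.88), CYP4B1 (5.62) and CHP2 (5.45) rose, and TFPI2 (-5.27), TACC3 (-4.65), the kinetochore gene NDC80 (-4.45), FOXM1 (-4.43) and DCBLD2 (-4.05) fell. The signals of these 5 genes at day 3 were near or under the pseudocount in at least 1 study, which sets the size and order of their falls, for example 10.7 and 4.22 for NDC80 and 17.5 and 14.7 for TFPI2 in the first and second study. At day 2 the same holds in the second study for CDC45 (12.3), DCBLD2 (19.3) and MYBL2 (19.6). With a pseudocount of 64 the day 3 changes were -4.01 for TFPI2, -3.53 for TACC3, -2.97 for NDC80, -3.29 for FOXM1 and -2.91 for DCBLD2, all past the test. These counts rest on 2 arrays per day. Without the second-study array of day -2 the number of genes changed day 1 against day -2 was 1, that of genes changed day 2 against day -2 was 58 and that of genes changed day 3 against day -2 was 264.

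The steps from day 0 to 1, from day 1 to 2 and from day 2 to 3 each gave 0 genes in limma, with 402, 385 and 397 genes at an unadjusted p under 0.05. With 4 residual degrees of freedom this does not show that neighbouring days were alike. Among the 573 genes higher after confluence by 2-fold or more, the median change from day -2 was 0.43 at day 0, 1.13 at day 1, 1.56 at day 2, 1.65 at day 3 and 1.5 at day 5. Among the 575 lower genes it was -0.24, -0.86, -1.5, -1.74 and -1.33. These genes were chosen for their change after confluence, and day 5 comes from the second study alone. The studies differed early: the median of the higher genes at day 0 was -0.000587 in the first study and 0.83 in the second, and at day 1 0.54 and 1.65. For the lower genes it was 0.12 and -0.54 at day 0, and -0.29 and -1.37 at day 1.

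Days measured once, each on 1 array of the second study, were set against their neighbours on the assumption that they vary like the shared days. Days -3 and -1 against day -2 gave 0 genes in limma, with 63 and 55 at an unadjusted p under 0.05. Day 5 against day 3 gave 0 in limma, with 667 at an unadjusted p under 0.05. Day 5 against day -2, a comparison added after seeing the data, gave 302 genes higher and 185 lower, and without the second-study array of day -2 the number of genes changed day 5 against day -2 was 52 in all. Without the second-study array of day 3 the count of genes changed day 5 against day 3 was 78, and it was 1 with the variance trend off and 1 with another choice of probe sets.

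The fourth comparison asked how far the second study gave the changes of the first. Across 7911 genes, which are not independent replicates, the mean change of days 1, 2 and 3 from day -2 correlated at r = 0.677 (Spearman's rho = 0.602). Of 941 genes changed 2-fold or more in the first study 91.9% had the same sign in the second and 64.2% also changed 2-fold or more there. Over all 7911 genes 71.0% had the same sign. At day 0 alone the correlation was -0.0465, with 51.8% of 357 such genes of the same sign, and at day 1 it was 0.377. Day 1 of the first study correlated at 0.385 with day 0 of the second and 0.377 with its day 1, day 2 at 0.669 with day 1 and 0.668 with day 2, and day 3 at 0.720 with day 2 and 0.651 with day 3. By the same mean over days 1, 2 and 3 from day -2, DSC1 changed by 5.13 in the first study and 5.29 in the second, KRT1 by 4.38 and 3.60, and FLG by 2.07 and 4.51, differences between the studies that were not tested on these days.

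**Figure D3:**
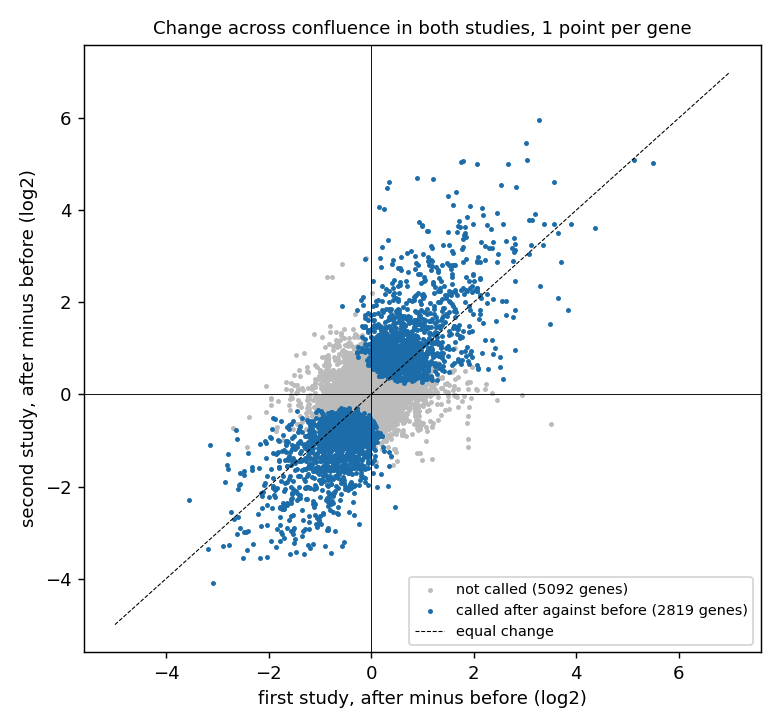
Log2 change after against before confluence in the first study (x axis) and the second (y axis), with 1 point per gene for 7911 genes. The 2819 called genes lie mostly in the quadrants of equal sign.

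The U133B array, used in the first study alone, holds mostly other probe sets, some of them for genes that the other arrays measure as well. Limma called a slope over the 5 days for 67 genes that rose and 6 that fell of 7076 (1224 at an unadjusted p under 0.05). Among the largest rises, the mucin MUC15 changed by 6.95 from day -2 to day 3 (slope 1.44 per day, SE 0.11, adjusted p = 0.00105), DAPL1 by 6.27, the kinase PDK4 by 5.48 (from a signal of 20.6, near the pseudocount, and by 4.31 with a pseudocount of 64), the keratin KRT77 by 5.41, KRTDAP by 5.27, AADACL2 by 5.15, SBSN by 5.05 and GPR15LG by 4.70. The falls were FST, an activin antagonist, at -4.58, ADAMTS1 at -4.38, THBS1 at -3.31, HIVEP3 at -2.47, INHBA, an activin subunit, at -2.08 and PMEPA1 at -1.65 (a call lost in 12 of 16 alternatives).

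Of these, FST, THBS1, INHBA and PMEPA1 were also called on the 13 other arrays, at -2.65, -3.12, -1.88 and -1.76. ADAMTS1 was not (adjusted p = 0.609), with -2.05 in the first study and 0.18 in the second. The 100 probe sets shared by U133A and U133B had changes from day -2 that correlated across probe sets at r = 0.555 at day 0, 0.680 at day 1, 0.924 at day 2 and 0.966 at day 3. The U133B calls rest on single arrays: limma called 0 without day 3 (733 at an unadjusted p under 0.05) and 0 with days 1, 2 and 3 set against day -2 (554). The slope of U133B gene HIVEP3 was 0.445 without day -2. Of 60 orders of the days, with each paired with its reverse, 3 gave as many genes, the real one included.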

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

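The tests of the study difference, the melanocyte genes and the Dap control were chosen after the values had been seen, as were the splits within each study, the splits for each list and the count of 120 day orders for U133B. A first form of the test of a delay, on single arrays, and one of array scaling, on the median of all genes, were replaced after their results were seen. The splits over both studies and a count of 60 day orders for U133B were set before.

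For the number of genes changed after against before confluence, 1 of 100 splits of the arrays, the real one, gave 2819 genes. The highest other gave 2082, with the first-study array of day 1 in the place of that of day -2. With arrays exchanged within each study alone, 1 of 100 splits, the real one, gave as many genes. The highest other drawn gave 1972, with the latest days of each study in the place of those before confluence. A random grouping of the arrays is thus excluded for this number. The arrays are ordered days, so any drift with time would also set the real split apart, and the splits cannot tell it from confluence. Chance cannot be excluded for the number of called lists, since 30 of the 100 splits over both studies, and 26 of the 100 within each study, called at least the 13 of the real one, and the highest other called 17 in both. For the slope on U133B the answer turns on how orders of the days are counted. As set before, with each order paired with its reverse, 3 of 60 gave at least the 73 genes of the real order, which does not exclude chance. With the 120 orders counted singly, since the days are not evenly spaced, 4 did, and the highest other gave 493. The second count is under the limit, but it was made after the first was seen, so chance is not taken as excluded. Above the real order lay its reverse (404 genes) and that reverse with days 2 and 3 exchanged (493). The real order with days -2 and 0 exchanged gave 191. These orders keep most of the order in time, so their counts say little on chance.

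Single lists were also set against the 100 splits over both studies, by the size of their median in either direction. A random grouping of the arrays is excluded, before any correction for the 26 lists, for 10 of the 13 called lists. Here too a drift with time cannot be told from confluence. The real split alone, 1 of 100, was as large for the lists of cornified envelope (2.26, highest other 1.74), DNA replication (-1.78, highest other 1.73 in size), proteases and inhibitors (1.22, 1.10), antimicrobial genes (1.51, 1.47), differentiation transcription factors (1.11, 0.95) and lysosome and autophagy (0.65, 0.62). The count was 2 for suprabasal keratins and desmosomes (1.35, 1.41), ribosome biogenesis (-0.82, 0.86 in size) and melanocyte markers (1.16, 1.36), and 3 for mitosis (-2.25, 2.40 in size). Such a grouping is not excluded over both studies for activated keratinocyte and wound (5 of 100, -0.92, 1.23 in size), barrier lipid synthesis (5 of 100, 0.53, 0.83) and ribosomal proteins (11 of 100, 0.32, 0.51). For activated keratinocyte and wound the count was 3 of 100 with arrays exchanged within each study, under the limit of 5. Its answer thus turns on the splits used. Adjusted over the 26 lists, 6 of the 13 stay under 0.05, those with a count of 1. The 10 lists with a count under 5 over both studies also had one under 5 with arrays exchanged within each study. There the count was 5 for barrier lipid synthesis and 7 for ribosomal proteins.

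A test of the difference between the studies, an interaction of study and phase, called 6 lists with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.726). Mitosis genes changed by a mean of -1.08 in the first study and -2.63 in the second (adjusted p = 2.24e-08), and genes of DNA replication by -1.11 and -1.92 (adjusted p = 0.000353). The lists of differentiation transcription factors (0.88 and 1.65, adjusted p = 0.00312), oxidative phosphorylation (0.40 and -0.04, adjusted p = 1.45e-05), ribosomal proteins (0.64 and 0.16, adjusted p = 0.000209) and melanocyte markers (0.16 and 1.34, adjusted p = 0.00812) differed as well. Of single genes 1 of 7911 passed, NAT9 (2.46 in the first study and -0.13 in the second, adjusted p = 0.0305), named after its value was seen.

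For the smaller fall of the mitosis and replication genes in the first study, neither explanation tested was excluded. For a general compression of folds on U133A, the second study was scaled by the ratio of SDs over all other genes, and the first then lay 0.94 above it for mitosis and 0.36 for replication. The SEs across genes were 0.09 and 0.10 with genes taken as independent, and 0.49 and 0.42 with their correlation allowed for. That correlation came from a fit with no term for a study difference, so the difference tested widens its own SE. The first pair is too narrow and the second may be too wide, so the test cannot decide. A first study running about 1 day behind cannot be told apart from other explanations either. With the changes of days 1, 2 and 3 from day -2 in the first study set against those of days 0, 1 and 2 from day -3 in the second, the mean differences were 0.483 for mitosis and 0.476 for replication, but single day pairs went as low as 0.18 and 0.30. A difference between cultures stays open and was not tested, and the first study has 1 array before confluence.

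In the second study the melanosome genes MLANA (1.83), PMEL (2.04) and TYRP1 (1.46) were higher after confluence by similar amounts, a range of 0.583 that a larger share of melanocytes in the later cultures may give. Their signals there went from 75.9 to 331, from 127 to 591 and from 719 to 1964. A common scale factor cancels in the mean of the list minus that of all other genes on the same array, which over both studies was higher by 0.98 (SE 0.33) after confluence, and the list was still called after quantile normalization (adjusted p = 0.0237). This is above the 0 that a common scale factor alone would give, which argues against such a factor for this list. It is nearly equal to the list's own mean change of 0.982, but that carries no weight. Scaling each array to a common mean holds the other genes nearly fixed. The test as set could not tell, because the error, a spread over arrays, reaches below its limit of 50% of the list's mean change. A change within melanocytes stays open, and TYR (0.94) and SLC45A2 (0.25), both dim, had smaller values in that study.

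The Dap control, a bacterial transcript whose probe sets were left out of the fits, read 30543 at day 3 on U133A of the first study against 11478 at day -2. Scaling is argued against, because the ratio of Dap to the CreX control, added at hybridisation, was 2.46 times higher at day 3 than at day -2 on U133A and 1.70 times on U133B. A smaller share of mRNA in the total RNA of confluent cells would recur in the second study and stays open, since the controls there do not give 1 answer. After confluence against before it, the ratio to CreX was 1.11 times higher for Dap, 1.09 for Phe and 1.10 for Thr but 1.41 for the Lys control, and that of Dap was 1.53, 1.36, 1.23 and 0.939 times its day -2 value at days 1, 2, 3 and 5. An unequal amount of control RNA between labelling reactions was not tested and may remain.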

How the results depend on the processing

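Leaving out the arrays with a high ACTB ratio and setting day 5 against day -2 were chosen after seeing the data, and all other alternatives were set before. Of 110 named genes on the U133A and U133A2 arrays 107 were called, and these kept their sign in each of the 30 alternatives other than U133A alone that gave them a value. A value came from all 30 for 82 genes, of which 63 kept their call throughout, and from 24 or more for the other 25, of which 18 kept it where measured. Calls were lost in 8 alternatives for NDUFS1, 6 for CCN2, 5 each for COX5B, OAS1, OAS3 and S100A4, 4 each for IVL, PMEPA1 and SDHD, 3 each for DST, IFI35, MLANA and SC5D, 2 each for ACAT2, HES1, LCE2B, PMEL and TFPI2, and 1 each for CALR, CDKN1C, FOXM1, MITF, NDC80, TACC3, TGM2 and TNFAIP3. Quantile normalization and median centring moved the median of all genes by under 0.02. Signal over background limits dim genes, and no detection calls were used here. Except where the construction shows it (fewer arrays or genes, a 2-fold limit), the cause was not tested.

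The counts of genes higher after confluence and genes lower after confluence were 790 and 952 with no replicate block, 0 and 0 with U133A arrays alone (617 at an unadjusted p under 0.05), 746 and 682 with day 0 counted as after, 580 and 396 with only the 5 shared days, 573 and 575 with adjusted p and 2-fold, and 575 and 673 leaving out high ACTB ratio arrays.

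The count of genes changed day 1 against day -2 was 44 with quantile normalization, 46 with median centring, 9 with no trend and 0 with no replicate block (466 at an unadjusted p under 0.05). Leaving out each array gave 0 to 154 for it. With no replicate block, genes changed day 2 against day -2 numbered 62, genes changed day 3 against day -2 numbered 326 and genes changed day 5 against day -2 numbered 44, and leaving out each array gave 58 to 1275, 264 to 1514 and 52 to 701. Leaving out each array gave 0 to 1 for genes changed day 2 against day 1, 0 to 2 for genes changed day 3 against day 2 and 0 to 78 for genes changed day 5 against day 3. The last was 1 with probe sets without _x_at or _s_at preferred and 1 with no trend.

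Adjusted p values of lists moved across the limit as follows. For list activated keratinocyte and wound they were 0.0661 with the mean of probe sets, 0.0875 with probe sets without _x_at or _s_at preferred, 0.248 with U133A2 arrays alone, 0.0701 leaving out high ACTB ratio arrays and 0.00994 to 0.137 leaving out each array. For list barrier lipid synthesis they were 0.132 with the 60th percentile filter, 0.0523 with the mean of probe sets, 0.0773 with probe sets without _x_at or _s_at preferred and 0.0854 with U133A arrays alone. For list ribosomal proteins they were 0.0778 with quantile normalization and 0.000176 to 0.0900 leaving out each array. For list melanocyte markers the value was 0.562 with U133A arrays alone. For list unfolded protein response they were 0.0344 with no filter, 0.0451 with probe sets without _x_at or _s_at preferred, 0.0389 with only the 5 shared days and 0.0399 to 0.253 leaving out each array. For list basal keratins and matrix adhesion they were 0.0156 with U133A arrays alone, 0.0237 with a slope over days, 0.00686 leaving out high ACTB ratio arrays and 0.0495 to 0.404 leaving out each array. For list oxidative phosphorylation they were 0.000133 with U133A arrays alone and 0.0365 with only the 5 shared days, and for list p53 targets and arrest 0.0393 with U133A arrays alone.

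Camera with estimated correlation ended all 13 calls. The estimate was 0.836 for mitosis and 0.890 for ribosomal proteins. It comes from residuals that hold the differences between days of a phase and between the studies in their change. Members that move together over days thus count as correlated, and this setting cannot tell such movement from other correlation. It gave 0.174 for list cornified envelope and late differentiation, list suprabasal keratins and desmosomes, list epidermal proteases and inhibitors, list antimicrobial and alarmin, list differentiation transcription factors and list lysosome and autophagy, 0.454 for list activated keratinocyte and wound and list melanocyte markers, 0.213 for list DNA replication, 0.318 for list mitosis, 0.31 for list barrier lipid synthesis, 0.646 for list ribosomal proteins and 0.200 for list ribosome biogenesis.

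The count of U133B genes higher over days was 40 with no filter, 35 with the mean of probe sets, 3 with no trend and 0 with days 1, 2, 3 against day -2 (554 at an unadjusted p under 0.05 in either direction), and 0 to 200 leaving out each array. The count of U133B genes lower over days was 27 with pseudocount 64, 31 with quantile normalization, 3 with no filter, 24 with the 60th percentile filter, 2 with the mean of probe sets, 0 with no trend, 0 with days 1, 2, 3 against day -2 and 0 to 224 leaving out each array. The counts were 200 and 224 without day -2, 5 and 0 without day 2, and 0 and 0 without day 3. The slope of U133B gene HIVEP3 was 0.168 with probe sets without _x_at or _s_at preferred, and ran from -0.56 to 0.445 leaving out each array, the last without day -2. Each named U133B gene lost its call in some alternatives. Losses were most frequent for PMEPA1 (12 of 16), AADACL2 (8 of 16) and HIVEP3 (7 of 15), and least for MUC15 (2 of 16) and PDK4 (2 of 14).

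The agreement Pearson r was -0.0465 with day 0 alone and 0.377 with day 1 alone. The agreement same-sign percent was 77.7 with no filter, 51.8 with day 0 alone and 74.8 with day 1 alone.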

Other observations

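All patterns here were looked for after the data had been seen. Interferon response genes stood low at day 3 of the second study, on 1 array with no replicate. The ratio of 3′ to 5′ signal of the GAPDH control, a measure of RNA integrity, was 1.37 on that array, the highest of the 18, against 1.23 at days 2 and 5. Against the mean of days 2 and 5, the median of the 28 genes was -0.83 (percentile 0 among 10000 random lists matched on signal, which leave out the correlation between members). Mitosis (-0.79) and DNA replication genes (-0.50) were at percentile 0 by the same measure, so it does not single out the interferon genes. IFIT1 stood at -2.76, RSAD2 at -2.65 (with a signal of 11.3 on that array, under the pseudocount), OAS2 at -1.97 and ISG15 at -1.85. From day 2 to day 3 the list changed by -0.74 in the second study and by 0.03 in the first, a difference that was not tested. From day 3 to day 5 the list was higher by a median of 1.32, with 16 of 28 genes up 2-fold or more.

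Day 5 was measured once and was set against day 3 as a description of these 2 arrays. Mitosis and DNA replication genes were higher at day 5, by medians of 0.81 and 0.62 (percentile 100 among the random lists for both), with TOP2A at 1.22, PCNA at 1.52 and MCM2 at 1.15. The percentile does not single them out, since proteases and inhibitors (0.58), antimicrobial and interferon response genes were at 100 as well, and cornified envelope, barrier lipid, wound and cholesterol genes were at 99.99, 99.97, 99.92 and 99.91. Antimicrobial genes were higher by a median of 0.73, with the alarmin S100A9 at 3.09 but its partner S100A8 at 0.45. Of the cytokine genes looked at, the chemokine CXCL8 stood at 3.22 and IL1B at -0.41. Ribosomal protein genes were lower by 0.43 (percentile 0). The immediate early genes changed by a median of 1.22 from day 2 to day 3 in the second study and by 0.06 in the first. Members did not move as 1 group over that step in the second study, on 1 array per day. The signal of FOS went from 398 to 217 and that of EGR1 from 2001 to 1096, while that of DUSP1 went from 3662 to 8585.

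The keratins did not move as one family, on values given with no weighing. Beside KRT1, KRT10 and KRT4, KRT23 rose by 3.59 (SE 0.89), KRT2 by 2.05 (SE 0.53), KRT16 by 1.56 (SE 0.27) and KRT13 by 0.97 (SE 0.16), while KRT15 did not pass the test (1.5, SE 0.78, adjusted p = 0.152 in limma). Its mean over the days after confluence hides a rise and a fall in the second study, on 1 array per day. There its signal went from 683 at day -2 to 8923 at day 1 and 307 at day 5. In the first study it went from 3398 at day -2 to 12112 at day 3. The simple epithelial keratins KRT19, KRT8 and KRT18 fell by 2.61 (SE 0.74), 1.45 (SE 0.52) and 1.15 (SE 0.26), with KRT7.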
